A study of Mus musculus with 4 samples.

How the data were processed

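Counts of UMIs per gene and barcode were deposited by the authors as 1 matrix per group, without normalization. They come from a droplet 5' single-cell kit (10x Genomics, chemistry version 2) and a NovaSeq sequencer, per the labels' protocols. Cell Ranger 4.0, Seurat 3.2.0 and the mouse build mm10 are named per the submitters' processing notes, and the matrices were written by Cell Ranger 4.0.0 per the file headers. The role of Seurat, the annotation release, the alignment options and any filter on cells beyond Cell Ranger are not given in the sources used here. The values were whole numbers, the totals differed between the matrices, and the smallest barcode total was 500 in both. T cell receptor sequence libraries, which the labels' protocols also mention, were not used here. The labels give 4 entries in 2 groups, with 2 entries per group that differ in an index and lane tag. Each group has 1 matrix whose barcodes all end in the suffix 1, and 133 barcodes occur in both matrices. No map from cells to entries was used here, so each group is 1 sample. For this reason no test, p-value, standard error or count of genes from a test was computed.

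Cells were kept with at least 200 genes, at least 500 UMIs and under 10% of UMIs from the 13 mitochondrial genes. This removed 167 of 10784 control barcodes and 193 of 10183 IL-27 barcodes. Doublets were scored per matrix with Scrublet as implemented in scanpy 1.11.5, with an expected rate of 8%. It called 0 of 10617 control cells (score threshold 0.744) and 167 of 9990 IL-27 cells (1.67%, threshold 0.338). A caller that marks no cell among so many has not worked, so doublets remained in the control matrix, and values with no doublets removed and with the 8% of highest scores removed from each matrix (849 and 799 cells) were computed as alternatives. The kept cells held 53836151 and 42793875 UMIs.

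Both matrices were clustered together: counts were scaled to 10000 per cell and logged, 2000 variable genes without T cell receptor and antibody segment genes were taken, 30 principal components and 15 neighbours with Jaccard weights were computed, and Leiden clustering ran at resolution 1.0 with seed 0. This gave 26 clusters, of which 2 stayed unnamed. The T and NK clusters were clustered again by the same steps into 12 clusters, called T/NK clusters, of which 5 stayed unnamed. Names come from 23 marker sets. A cluster took the class with the highest mean score over the class's markers, with at least 3 markers detected at 50 CPM, and a score of at least 0.5 in the first round. Where none of the class's markers was among the cluster's 10 leading genes, at least 50% of the markers had to be raised 1.5-fold and the score had to lead the next class by 1.0 in the first and 0.5 in the second round. It stayed unnamed where more of its 10 leading genes were markers of another class. These thresholds, and a rule that clusters with Cd3e of at least 200 CPM cannot be called innate lymphoid or NK cells, were set after the data were seen. Under first versions of the rules part of the Treg-like cells took the innate lymphoid name in some settings. T cells were all T/NK clusters with Cd3e of at least 200 CPM and no lead by genes of another lineage. Classes are called "like" because they rest on transcripts alone.

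UMIs were summed per matrix and class and divided by the class total to give CPM. Shares have exact Clopper-Pearson intervals, CPM exact Poisson intervals and ratios exact conditional binomial intervals, all at 95%. Where a count was 0, a floor of 3 counts was used, which lies below the upper end of the two-sided Poisson interval. For 22 gene lists the median log2 ratio was taken over members with at least 20 UMIs in the class, with an interval from 2000 Poisson redraws and the percentile of the median among 10000 random lists of the same size drawn within 20 bins of mean expression. The percentile describes these 2 libraries. The lists cover Treg identity, the Th1 and interferon gamma programme, IL-27 signalling, interferon-stimulated genes, co-inhibitory receptors, exhaustion, naive and stem-like cells, cytotoxic effectors, proliferation, type 17, type 2, follicular helper, MHC class I, MHC class II, inflammatory macrophage, alternative macrophage, chemokines, checkpoint ligands, glycolysis and hypoxia, oxidative phosphorylation, dissociation and stress, and housekeeping genes. Listed symbols with no match were Mx1, Cd244, H2az1, Cxcl11 and Ero1a. A list member counted as higher or lower at a ratio of at least 1.5 in either direction. A single gene is called higher or lower where its interval lies off 1, and its ratio or levels show the size. Genes were named by a fixed rule. They needed at least 50 UMIs in the matrix with the higher CPM and UMIs in at least 5% of its cells of a class with at least 50 cells per matrix. Mitochondrial, ribosomal, receptor segment, hemoglobin and model genes and markers of other classes were left out. The 10 highest and 10 lowest ratios were taken in Treg-like, CD8 T-like and neutrophil-like cells and the 5 highest and 5 lowest elsewhere, with up to 4 extreme members per list and class and 12 genes fixed for the fragility question, of which 1 is not reported here. The text gives a selection of these. Prf1, Pdcd1 and Havcr2 in CD8 T-like cells, Xcl1 in Trbv4 cells, Lyz2, C1qa, S100a9, G0s2, Cd4, Areg, Il1rl1, Cd8a and Klrd1 as genes of other cell types and the members named in T/NK cluster 1 were chosen after their values were seen. So was Cd3e in Treg-like cells. The share of a gene's UMIs held by the 3 cells with most of them was computed for part of the genes the text names, also after their values were seen. Shares of cells with a UMI were compared after thinning each cell to 1000 UMIs. The samples, designs, lists, markers, the naming rule for genes and the first set of other settings were fixed before the data were examined.

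Gene coordinates, transcript lengths and GC content came from GENCODE M21 (GRCm38, the assembly of mm10), in which 32158 of 32285 genes (99.6%) were matched. A quadratic trend of the log2 ratio on length, GC and mean level was fitted per class and removed as an alternative chosen after the data were seen. The statistics were tested on simulated data. In the Treg-like simulation (9138 genes), 200 genes were altered, some by 3-fold and the others by 1.5-fold, in either direction. Ratio intervals covered 96.2% of true values. The direction was recovered for 100% of the genes altered by 3-fold. Of these genes 97.9% passed the 1.5 rule, as did 8.80% of unaltered genes, and 4 of 100 null lists lay outside percentiles 2.5 to 97.5. In the neutrophil-like simulation (9540 genes) the values were 95.9%, 100%, 100%, 7.85% and 5 of 100. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, used only for TMM scaling factors.

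The other settings chosen at the start were a stricter cell filter (500 genes, 1000 UMIs, under 5% mitochondrial), no mitochondrial limit, doublets kept, clustering resolutions 0.5 and 2.0, seed 1, scaling by median gene ratios, by TMM or without mitochondrial, ribosomal, hemoglobin and receptor segment genes, the mean of CPM per cell, list minimums of 0 or 100 UMIs, naming minimums of 20 or 200 UMIs, and Tregs by a Foxp3 UMI with and without thinning. Alternatives chosen after seeing the data were removal of the 8% of cells with the highest doublet scores, the trend removal, CD8 cells by a Cd8a or Cd8b1 UMI without a Cd4 UMI, and CD8 T-like cells led by Trbv4 alone.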

Results

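Single-cell RNA sequencing measured the transcripts of cells that a bead sort for CD45 (a surface protein of blood-derived cells) had enriched from mouse tumours. The tumours grew under the skin of B6C3F1 mice from OV2944-HM1, a mouse ovarian cancer line. One group received vehicle (control) and the other 100 ng of recombinant mouse interleukin 27 (IL-27) per mouse into the tumour every other day. Cells were collected on day 14. The labels list 4 entries, 2 per group, but each group was 1 matrix of counts with no map from cells to entries, so n = 1 per group, no test was possible, and no difference has a replicate check. The control matrix held 10784 barcodes with 54049661 UMIs (unique molecular identifiers, 1 per captured transcript) and a median of 2384.5 per barcode. The IL-27 matrix held 10183 barcodes with 43868189 UMIs and a median of 1847. After filtering, 10617 control cells and 9823 IL-27 cells remained. The series title asks whether IL-27 makes regulatory T cells (Tregs) fragile, which is usually described as loss of suppression with gain of interferon gamma while Foxp3 is kept, and how this bears on checkpoint blockade. Intervals are at 95% and cover counting error only. They are exact for shares and ratios (Clopper-Pearson) and for levels (Poisson), and those of list medians come from Poisson redraws of the counts. Ratios are IL-27 over control.

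The first question was which cells the tumours held in each group. Neutrophil-like cells were the most frequent class in both matrices and macrophage-like cells came next. The IL-27 matrix had larger shares of Treg-like, natural killer (NK)-like and mature dendritic-like cells and a smaller share of CD8 T-like cells. Neutrophil-like cells made up 47.6% (46.7 to 48.6) of control cells and 41.6% (40.6 to 42.5) of IL-27 cells. Macrophage-like cells made up 19.3% and 18.7%, a ratio of 0.968 (0.908 to 1.03), but 10.9% and 11.3% when the 8% of cells with the highest doublet scores were removed. Monocyte-like cells made up 5.88% and 7.14%, a ratio of 1.21 (1.09 to 1.36), but 15.5% and 18.2% at a coarser clustering resolution, so the sizes of these 2 classes depend on the processing. Treg-like cells numbered 222 and 344, which is 2.09% (1.83 to 2.38) and 3.50% (3.15 to 3.88). CD8 T-like cells numbered 207 and 79, which is 1.95% (1.70 to 2.23) and 0.804% (0.637 to 1.00), a ratio of 0.412 (0.314 to 0.537). NK-like cells made up 0.970% and 1.71%, a ratio of 1.76 (1.37 to 2.28). All dendritic-like cells together made up 5.74% and 7.33%. Within them, mature dendritic-like cells had a ratio of 1.73 (1.44 to 2.08), conventional type 1 cells a ratio of 0.998 (0.848 to 1.17), and conventional type 2 cells a ratio of 1.30 (0.994 to 1.70). Mast cell or basophil-like cells had a ratio of 0.806 (0.541 to 1.20), and gamma-delta T-like cells numbered 18 and 13. With no mitochondrial limit the latter numbered 73 and 124, so no direction is given for them. An eosinophil-like cluster held 2 control cells and 60 IL-27 cells with median UMIs of 608.5 and 570.5.

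**Figure D1:**
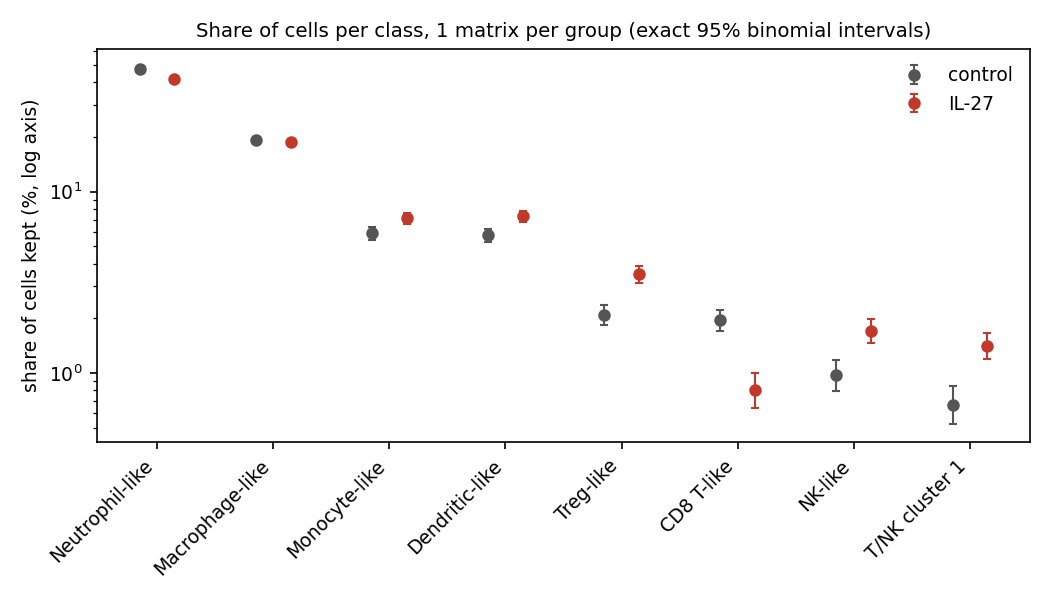
Share of all cells kept (percent, log axis) in the control and IL-27 matrices, with exact 95% binomial intervals. Drawn are neutrophil-like, macrophage-like, monocyte-like, dendritic-like, Treg-like, CD8 T-like and NK-like cells and the unnamed T/NK cluster 1. CD8 T-like cells lie at 1.95% and 0.804%, Treg-like cells at 2.09% and 3.50%.

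Cells that a CD45 sort should remove were also present. Tumour-like cells, defined by keratin genes such as Krt8 and Krt18, made up 2.55% and 2.03% with median UMIs of 43741 and 47756, and their ratio of 0.794 (0.658 to 0.957) was 1.00 when the 8% of cells with the highest doublet scores were removed. Fibroblast-like cells had a ratio of 1.24 (0.899 to 1.71). Endothelial-like cells had a ratio of 1.83 (1.27 to 2.66), which was 0.841 at a finer clustering resolution, so neither direction is given for tumour-like or endothelial-like cells. Without these 3 classes, the ratio for Treg-like cells was 1.67 (1.41 to 1.99) and that for CD8 T-like cells 0.413 (0.314 to 0.537). The 3 classes are a small and similar part of both matrices, so leaving them out could hardly move these ratios. Cluster 4, led by Ccl24, Mmp19 and Dcstamp, stayed unnamed and made up 6.71% and 8.93%. Cluster 11, led by Ngp, Camp and Ltf with dividing-cell genes, stayed unnamed and made up 2.36% and 2.11%. A plasmacytoid dendritic-like cluster (32 and 42 cells) also carried antibody genes such as Igkc and Jchain and was not compared.

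The sort, its yield and the depth gap (median UMIs 2408 and 1853 in cells kept) can move any of these shares. The median mitochondrial share of UMIs also differed, at 0.37% in control and 0.64% in IL-27 barcodes. Neutrophil-like cells spanned 4 clusters, 1 led by stress genes such as Egr1 and Dusp1 and 1 by interferon-stimulated genes such as Rsad2 and Isg15, and a macrophage-like cluster was led by Hspa1b and Hspa1a, so the sizes of these clusters were not compared.

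The second question was whether regulatory T cells were more or less frequent among T cells. Treg-like cells made up 36.0% (32.2 to 40.0) of 616 control T cells and 51.7% (47.8 to 55.5) of 666 IL-27 T cells, a ratio of 1.43 (1.21 to 1.70). CD8 T-like cells made up 33.6% (29.9 to 37.5) and 11.9% (9.505 to 14.6), so the balance between the classes lay far apart in the matrices. Fewer CD8 T-like cells by themselves raise the Treg-like share of T cells, and how much of the ratio of 1.43 follows from them was not computed. The Treg-like share of all cells kept, which hardly depends on the number of CD8 T-like cells, was also higher, with a ratio of 1.675 (1.41 to 1.99). The Treg-like class held T/NK clusters 0 and 9, the second of which was led by histone and dividing-cell genes, and the CD8 T-like class held T/NK clusters 2 and 6. Counting cells with a Foxp3 UMI in place of clusters gave 34.6% (30.8 to 38.5) and 45.9% (42.1 to 49.8). With every cell thinned to 1000 UMIs, the same gate gave 100 of 592 cells (16.9%) and 165 of 639 cells (25.8%). The other T cells lay in T/NK cluster 1 (11.5% and 20.9% of T cells), T/NK cluster 4 (12.99% and 9.91%) and T/NK cluster 10 (2.92% and 3.75%), which stayed unnamed. T/NK clusters 5 and 7 carried Cd3e beside neutrophil genes (S100a9, S100a8) or antigen presentation genes (H2-Ab1, Cd74). Thresholds set after the data were seen kept these 2 clusters out of the T cells, and they made up 0.509% and 0.471% of control cells and 0.255% of IL-27 cells each.

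The third question was whether Treg-like cells of the IL-27 matrix carried a fragile profile. They did not show interferon gamma transcripts, and the inhibitory receptor genes Pdcd1 and Ctla4, each by just under 1.5-fold, and the Th1 regulator gene Tbx21 were lower. Cd3e, a gene of T cells at large, was lower too, with a ratio of 0.714 (0.665 to 0.767), as were housekeeping genes. Part of the lower Pdcd1 and Ctla4 can therefore belong to a wider shift. Foxp3 was level, but it is among the markers that named the class, so a loss of Foxp3 cannot be tested in this way. Ifng (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892, plus strand, GRCm38), the gene of interferon gamma, had 0 UMIs in 222 control and 344 IL-27 Treg-like cells. By the limit of 3 counts that is set on a count of 0 here, this allows levels of up to 1.86 and 1.46 CPM, or UMIs in up to 1.35% and 0.872% of cells. A difference in Ifng was therefore not detectable at this depth. Among T cells with a Foxp3 UMI, Ifng had 16 UMIs in 1 control cell and 30 UMIs in 2 IL-27 cells, all of them in CD8 T-like clusters. Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245, plus strand), which encodes the lineage factor of Tregs, stood at 594 CPM (557 to 633) and 585 CPM (553 to 620), a ratio of 0.986 (0.904 to 1.07). Pdcd1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553, minus strand), the gene of the receptor PD-1, stood at 398 CPM (368 to 430) and 266 CPM (244 to 289), a ratio of 0.669 (0.595 to 0.751). Ctla4 (ENSMUSG00000026011, chromosome 1, 60887000 to 60915832, plus strand) stood at 1489 CPM (1430 to 1549) and 994 CPM (952 to 1038), a ratio of 0.668 (0.629 to 0.709). Tbx21 (ENSMUSG00000001444, chromosome 11, 97098071 to 97115331, minus strand) had 30 and 18 UMIs, or 18.6 and 8.78 CPM, a ratio of 0.473 (0.248 to 0.876). Cd8a, which Tregs should lack, had 9 and 2 UMIs in the same cells, so other T cells can add to the Tbx21 counts.

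Cxcr3 (ENSMUSG00000050232, chromosome X, 101731535 to 101734269, minus strand), a chemokine receptor gene of Th1 and activated cells, stood at 63.8 and 46.8 CPM, a ratio of 0.734 (0.550 to 0.979). Higher in the IL-27 matrix were Il2ra (ENSMUSG00000026770, chromosome 2, 11642807 to 11693193, plus strand), with 722 and 930 CPM, and Ikzf2 (ENSMUSG00000025997, chromosome 1, 69531214 to 69687245, minus strand), with 1030 and 1519 CPM. Their ratios were 1.29 (1.20 to 1.38) and 1.47 (1.39 to 1.57), both under 1.5-fold. Ctla4, Il2ra, Ikzf2 and Foxp3 are also among the markers that named the class. The intervals of 3 genes held 1: Nrp1 (ENSMUSG00000025810, chromosome 8, 128358604 to 128503363, plus strand) with a ratio of 1.02, Il10 (ENSMUSG00000016529, chromosome 1, 131019845 to 131024974, plus strand) with 0.788, and Il27ra (ENSMUSG00000005465, chromosome 8, 84030294 to 84042589, minus strand), which encodes the IL-27 receptor, with 1.18.

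Shares of cells with a UMI were compared after thinning to 1000 UMIs, which left 216 control and 333 IL-27 Treg-like cells and left out 6 and 11. Pdcd1 was seen in 31.5% (25.3 to 38.1) and 23.1% (18.7 to 28.0) of thinned cells, against 70.7% and 54.4% before thinning. Ctla4 was seen in 67.6% and 58.6% (91.9% and 87.8% before thinning), and Foxp3 in 45.8% and 46.3% (86.9% and 84.3% before thinning). Cxcr3 was seen in 5.56% and 5.71% and Tbx21 in 1.39% and 1.502%, so a difference in cell shares was not detectable for these 2 genes at this depth. Neutrophil-like cells, which should lack these genes and had median UMIs of 2111 and 1560 beside 4876 and 3970 in Treg-like cells, showed Pdcd1 in 0% of thinned cells of either matrix, Ctla4 in at most 0.122% and Foxp3 in at most 0.122%.

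**Figure D2:**
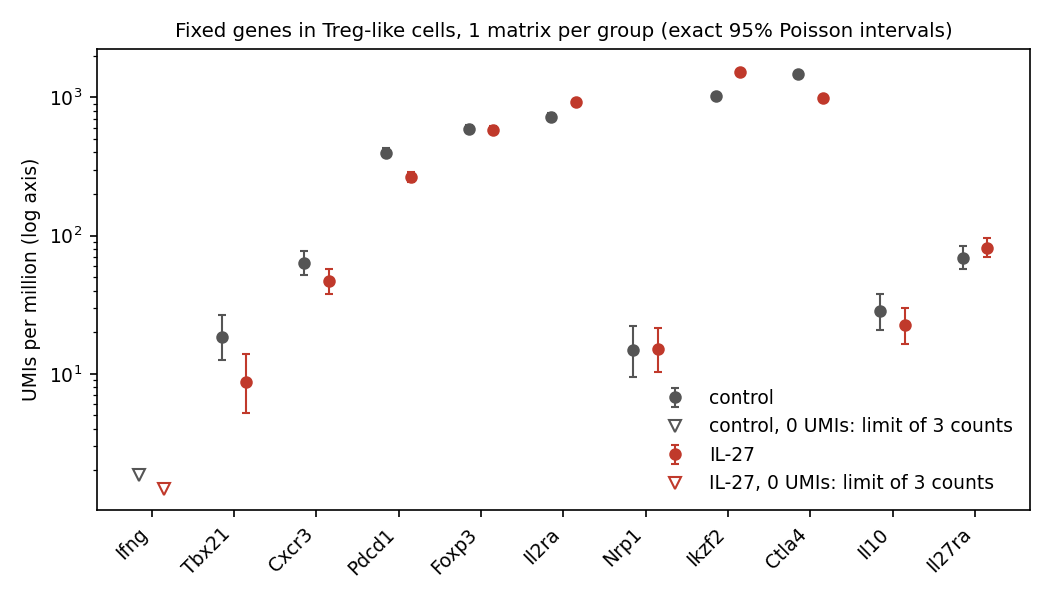
Levels (CPM, log axis) of the genes fixed for the fragility question in Treg-like cells of the control and IL-27 matrices, with exact 95% Poisson intervals. Ifng has 0 UMIs in both and is drawn as open triangles at the limit of 3 counts, and Pdcd1 and Ctla4 lie lower in the IL-27 matrix at 266 and 994 CPM, by just under 1.5-fold each.

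Across gene lists, Treg-like cells of the IL-27 matrix had lower interferon-stimulated, MHC class I, cytotoxic and stress genes, while the Treg identity list was level. Housekeeping genes were lower to a similar degree (median -0.33), so these lists are not set apart from a wider shift. The Treg identity list had a median log2 ratio of -0.07 (-0.16 to 0.02) over 25 genes, at percentile 41.4 of 10000 random lists matched on mean expression. It holds the markers that named the class, Ccr8 among them, so a loss of Treg identity cannot be tested in this way. Within it, Il1rl1 (a marker of tissue Tregs that also led T/NK cluster 0) was higher at 157 and 372 CPM, Itgae was higher with a ratio of 2.01 (1.63 to 2.498), and the chemokine receptor gene Ccr8 was lower at 508 and 217 CPM, a ratio of 0.427 (0.380 to 0.480). The Th1 list had a median of -0.22 (-0.38 to -0.10) at percentile 2.38, which was -0.10 when the cells with the highest doublet scores were removed, and Il18r1 was its only gene at least 1.5 times higher. The interferon-stimulated list had a median of -0.31 (-0.38 to -0.15), below all random lists, and -0.55 both with no mitochondrial limit and with doublets kept. The co-inhibitory list had a median of -0.07 at percentile 35.6, with Tigit lower (ratio 0.578, 0.530 to 0.630) and Maf higher (ratio 1.73, 1.58 to 1.91). The IL-27 receptor and signalling list had a median of -0.07 at percentile 36.0. The cytotoxic list had a median of -0.40 at percentile 0.07. Its genes Gzma (143 and 39.5 CPM) and Prf1 (38.4 and 6.83 CPM) were lower beside Cd8a (5.58 and 0.976 CPM) and Klrd1 (11.2 and 1.95 CPM), which Tregs should lack, and 3 cells held 97.0% of the control UMIs of Gzma. Gzmc was higher (22.9 and 112 CPM), but its log2 ratio was -0.67 when the cells with the highest doublet scores were removed. Medians were -0.38 for MHC class I presentation (percentile 0), -0.24 for proliferation (0.5; -0.70 without the highest doublet scores), -0.29 for glycolysis and hypoxia (0.28), -0.19 for oxidative phosphorylation (4.85), -0.48 for dissociation and stress (0.01) and -0.33 for housekeeping genes (1.67). The MHC class II list was level at 0.02 (-0.29 to 0.13), but had -0.34 when the cells with the highest doublet scores were removed. By size (the extremes among genes that meet a fixed rule on counts and cells), Hist1h2an (ratio 6.06, 4.01 to 9.501) was highest but was seen in only 6.31% and 8.14% of cells. Rapgef2 (3.15), Pdk1 (2.92) and Prpf6 (2.71) were also higher.

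Part of these list medians goes with transcript length and GC content. In Treg-like cells, when genes were sorted by length into 5 equal groups, the shortest (median 1215 bases) had a median log2 ratio of -0.17 and the longest (7204 bases) 0.23, while the groups lowest and highest in GC had 0.12 and -0.12. All cells together showed the same slope (-0.11 and 0.20). With the length, GC and level trend removed, the Treg-like medians were 0.04 for Treg identity, -0.24 for Th1, -0.21 for interferon-stimulated genes and -0.35 for MHC class I, and the oxidative phosphorylation median was -0.07. Single genes had log2 ratios of -0.42 for Pdcd1, -0.57 for Ctla4, -0.99 for Tbx21, -0.26 for Cxcr3, 0.00 for Foxp3, 0.27 for Il2ra and 0.16 for Ikzf2.

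The fourth question was whether CD8 T-like cells differed. The 79 CD8 T-like cells of the IL-27 matrix had fewer transcripts of the exhaustion factor gene Tox, of Tbx21 and of several cytotoxic genes, and more of Il7r, the receptor gene of long-lived T cells. Ifng and several chemokine genes were higher in the summed counts, but a few cells held most of those counts. The cells also carried a different mix of T cell receptor beta V segments, so these values do not compare like cells. Trbv16 was the leading segment in 43.7% (36.6 to 50.9) and 6.15% (1.70 to 15.01) of CD8 T-like cells with such a UMI, and Trbv4 in 20.3% (14.9 to 26.6) and 66.2% (53.3 to 77.4). Tox stood at 132 and 73.8 CPM, a ratio of 0.562 (0.423 to 0.735), Tbx21 at 89.2 and 35.2 CPM, and Il7r at 99.3 and 277 CPM, a ratio of 2.79 (2.33 to 3.35). Genes of CD4 T cells and Tregs were higher beside Il7r, with Cd4 at 2.85 and 22.7 CPM (ratio 7.97, 3.24 to 22.3), Areg at 6.11 and 89.7 CPM, and Il1rl1 in 2 and 4 cells, so other T cells in the class can add to this. The exhaustion list had a median log2 ratio of -0.18 (-0.31 to -0.09) at percentile 3.89, in which Pdcd1 had a ratio of 0.860 (0.774 to 0.954) and Havcr2 a ratio of 1.42 (1.18 to 1.71). The naive and stem-like list had a median of 0.30 (0.22 to 0.95) at percentile 95. The cytotoxic list had a median of -0.16 (-0.26 to -0.01), which was -0.36 without the highest doublet scores, with 6 genes at least 1.5 times higher and 8 at least 1.5 times lower, and Prf1, the perforin gene, stood at 800 and 499 CPM. Interferon-stimulated genes were level at 0.07 (-0.12 to 0.16), proliferation lay at -0.01, and the glycolysis list was lower at -0.42. The unnamed T/NK cluster 4 scored highest for CD8 T cells, and its leading genes included Ifit1 and Ifit3. The level interferon-stimulated median therefore leaves out cells led by such genes. The dissociation and stress list was lower by more than the exhaustion list, with a median of -0.42 (-0.61 to -0.28) at percentile 0.04.

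Ifng stood at 50.1 and 143 CPM in CD8 T-like cells, a ratio of 2.86 (2.21 to 3.70), but 3 cells held 26.8% of its control UMIs and 65.1% of its IL-27 UMIs. After thinning to 1000 UMIs, Ifng was seen in 5.34% (2.70 to 9.35) and 7.60% (2.84 to 15.8) of cells, so a difference in the share of cells was not detectable. Before thinning it was seen in 27.5% and 30.4% of cells, with median UMIs of 9264 and 9789, and in 0% of neutrophil-like cells. The log2 ratio of Ifng was 0.57, and that of Tox -0.40, once the 8% of cells with the highest doublet scores were removed from each matrix. Ccl4 (84.7 and 515 CPM) and Ccl3 (50.5 and 225 CPM) were higher, but 3 cells held 94.7% and 89.4% of their IL-27 UMIs, and under that removal their log2 ratios were -1.35 and -0.12. For Ccl1, highest among genes that meet the naming rule (which leaves out Areg as a marker of innate lymphoid cells) with a ratio of 11.7 (7.47 to 19.2), 3 cells held 99.01% of the IL-27 UMIs, and its log2 ratio went from 3.55 to 1.01 under that removal. Gzmc (1089 and 226 CPM) and Gzmd (264 and 68.2 CPM) were lower, with 80.9% and 69.6% of their control UMIs in 3 cells. Under the same removal the Th1 list went from 0.19 to -0.01, Thbs1 from 2.48 to -0.19, and Maf from 3.24 to 2.69. The alternative macrophage list had a median of 1.39, which was -0.16 under that removal, beside more transcripts of the myeloid genes Lyz2 (13.4 and 57.9 CPM) and C1qa (5.29 and 27.3 CPM). Lowest by size were Upk1a, with 22.8 CPM beside 0 UMIs (which allow up to 3.41 CPM by the limit of 3 counts), and Rln3, with 57 and 1 UMIs and a ratio of 0.0490 (0.00122 to 0.284).

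**Figure D3:**
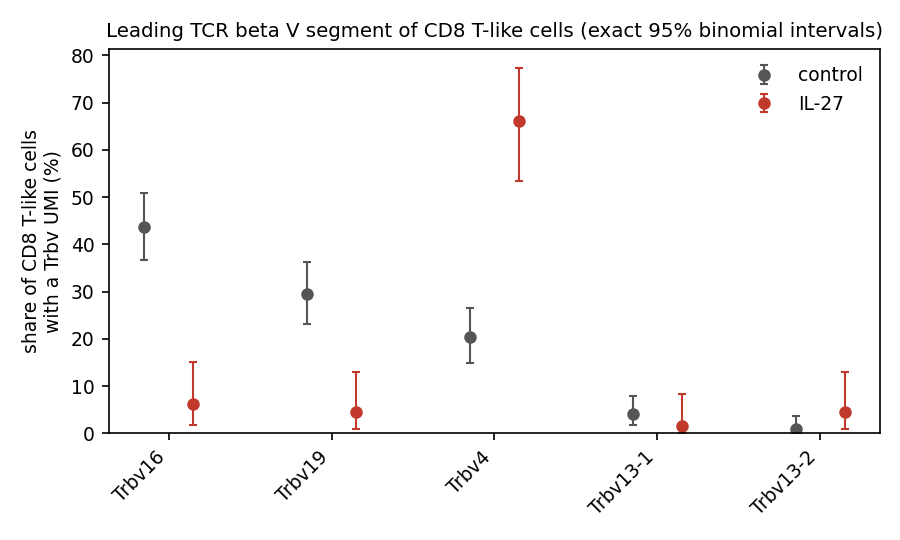
Share (percent) of CD8 T-like cells with a T cell receptor beta V UMI whose leading segment is the one named, in the control (197 cells) and IL-27 (65 cells) matrices, with exact 95% binomial intervals. Trbv16 leads in 43.7% of control cells and Trbv4 in 66.2% of IL-27 cells.

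The next question concerned the NK-like cells and T/NK cluster 1. NK-like cells of the IL-27 matrix, 168 beside 103 in control, had lower interferon-stimulated, cytotoxic and stress genes. The dissociation and stress list had the lowest median of the 3 at -0.60 (percentile 0), which was -0.37 with the length, GC and level trend removed. Their interferon-stimulated list had a median of -0.41 (-0.70 to -0.22) at percentile 0.04, led by Ifi27l2a at 155 and 29.3 CPM. The cytotoxic list had a median of -0.35 (-0.49 to -0.29) at percentile 0.31, with Gzmb at 2262 and 1187 CPM, a ratio of 0.525 (0.485 to 0.568), although 3 cells held 51.8% and 43.9% of its UMIs. Klrg1, a receptor gene of mature NK cells, was lower at 131 and 33.6 CPM. Gzmf stood at 57.9 and 1686 CPM, but 3 cells held 94.2% of its IL-27 UMIs, and it also led T/NK cluster 8 and had too few counts to compare once cells with the highest doublet scores were removed. Under that removal the log2 ratio of Mt1 went from 2.91 to -0.61 and the median of the proliferation list from 0.53 to -0.14. T/NK cluster 1 (71 and 139 cells), whose leading genes included Il4, Il5 and Tnfsf8, had a type 2 list median of 1.32 (0.68 to 1.73) over 6 genes. Of the members outside its leading genes, Il1rl1 stood at 50.9 and 166 CPM in 7 and 27 cells, with 73.3% and 30.9% of its UMIs in 3 cells, and Il13 was seen in 1 and 7 cells, with 79.4% of its IL-27 UMIs in 3 cells. Gata3 (ratio 1.16, 0.814 to 1.68) and Ccr4 (0.644, 0.368 to 1.14) had intervals that held 1. Its type 17 list had a median of -0.16 (percentile 23.9), its follicular helper list -0.56 over 3 genes (3.87) and its interferon-stimulated list -0.77 (-0.99 to -0.54).

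The last question was how the myeloid classes differed. Interferon-stimulated genes were lower in the IL-27 matrix in neutrophil-like, macrophage-like, monocyte-like and dendritic-like cells. The inflammatory list was lower in neutrophil-like, macrophage-like and dendritic-like cells. Housekeeping genes had medians of -0.19 (-0.30 to -0.08), 0.00 (-0.02 to 0.05) and -0.20 (-0.23 to -0.12) in these classes, so the neutrophil-like inflammatory median is not set apart from a wider shift. Neutrophil-like cells had an interferon-stimulated median of -0.42 (-0.50 to -0.37), with Ifit3b (ratio 0.3004, 0.241 to 0.372), Usp18 (0.422) and Zbp1 (0.452) lower. The class includes the cluster led by such genes, so this median does not separate a shift of cells between clusters from a shift within them. Slc7a11, a cystine transporter gene, stood at 1579 CPM (1556 to 1602) and 3319 CPM (3276 to 3362). Ugcg (2.69) and Olr1 (2.12), the second a lipoprotein receptor gene, were higher as well, and Phospho1 (0.236) and Snai1 (0.278) were lower. Among their cytokine genes, Cxcl1 had a ratio of 0.462 (0.448 to 0.476) and Il23a 0.559 (0.537 to 0.581). Their inflammatory list had a median of -0.24 (percentile 1.11), chemokines -0.14 (5.64), glycolysis -0.33 (0.01) and stress genes -0.46 (0). The leading genes of 1 cluster of the class included Egr1, Dusp1 and Hilpda, and those of another Il23a, Tnf and Ccl3. These 4 medians and the Il23a ratio thus do not separate a shift of cells between clusters from a shift within them either.

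Macrophage-like cells had an interferon-stimulated median of -0.54 (-0.61 to -0.34), with 15 of 33 genes at least 1.5 times lower, but -0.28 in cells without a UMI of 6 stress genes. Among them was Isg15, an antiviral ubiquitin-like gene, at 231 and 68.7 CPM. Their inflammatory list had a median of -0.47 (-0.53 to -0.25), which was -0.20 with no mitochondrial limit, with Nos2 (ratio 0.499, 0.409 to 0.604) and Il6 (0.542, 0.430 to 0.678) lower. The class includes a cluster led by Nos2, Rsad2 and heat shock genes, so neither median separates a shift of cells between clusters from a shift within them. The alternative list had a median of -0.04 and a mean of 0.10, with Lyve1 (14.5 and 47.5 CPM), a marker of resident macrophages, and Maf (162 and 304 CPM) higher. Medians were -0.29 for MHC class I (percentile 0.02), -0.13 for MHC class II (20.1), -0.27 for chemokines (0.05) and 0.02 for stress genes (79.8). The checkpoint ligand list was level at -0.03 (30.5), with Cd274, the gene of the ligand PD-L1, at 167 and 119 CPM, a ratio of 0.715 (0.636 to 0.802). The neutrophil genes S100a9 (286 and 136 CPM) and G0s2 (59.3 and 11.3 CPM) were lower in macrophage-like cells too.

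Monocyte-like cells had an interferon-stimulated median of -0.55 (-0.75 to -0.46), with Ifit1 (35.2 and 9.61 CPM), Oasl1 (82.3 and 24.2 CPM) and Siglec1 (15.7 and 4.12 CPM) lower. Genes of other cell types were lower beside them, with G0s2 at 84.5 and 21.4 CPM, S100a9 at 410 and 158 CPM and C1qa at 185 and 88.4 CPM. Their MHC class I and II lists had medians of -0.58 (-0.62 to -0.49) and -0.52 (-0.70 to -0.41), with Psmb9 at 204 and 117 CPM and Cd74 at 7854 and 4830 CPM. Gclm (ratio 3.65, 2.73 to 4.92) and Hmox1 (2.81, 2.45 to 3.23) were higher, and so was the chemokine gene Ccl24 (1.68), although the chemokine list had a median of -0.42. Dendritic-like cells had an interferon-stimulated median of -0.33 (-0.48 to -0.20), with -0.53 under a stricter cell filter and -0.21 in cells without a stress gene UMI, and an MHC class II median of -0.45 (-0.51 to -0.42), with Cd74 at 23274 and 15841 CPM. Mature cells were 191 of 609 control and 305 of 720 IL-27 cells of this class, so its medians also take in a different mix of subtypes. Their proliferation list was higher at 0.56 (0.38 to 0.67), which was 0.16 by the mean of CPM per cell, with Sox4 (ratio 3.50) and Egf (2.85) highest by size. Tnf (41.1 and 6.90 CPM), C5ar1 (19.9 and 3.73 CPM) and Il1a (45.1 and 13.8 CPM) were the lowest in dendritic-like cells among genes that meet the naming rule, which leaves out genes with few counts and markers of other classes, beside less of the myeloid genes S100a9 (165 and 95.7 CPM) and C1qa (19.9 and 6.71 CPM). Their inflammatory list had a median of -0.37 and their stress list -0.52.

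**Figure D4:**
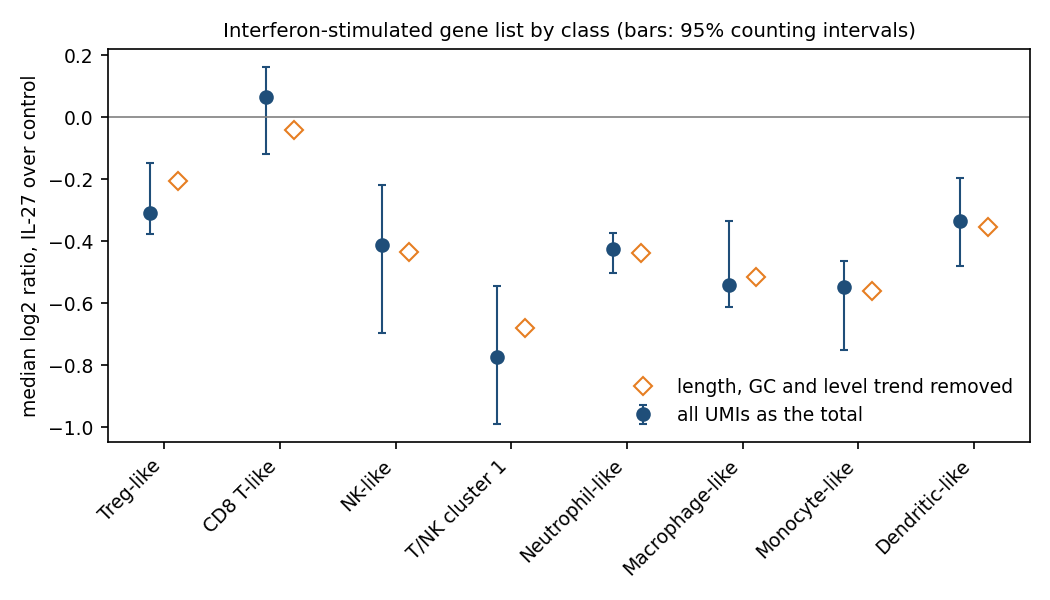
Median log2 ratio (IL-27 over control) of interferon-stimulated genes in each class, as filled points with 95% intervals from Poisson redraws of the counts and as open diamonds with the length, GC and level trend removed. CD8 T-like cells lie at 0.07, and the other classes from -0.31 in Treg-like cells to -0.77 in T/NK cluster 1.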

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

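The tests of doublets kept and of the few frequent T cell receptor segments were chosen only after the results they measure had been seen, and the T cell receptor and eosinophil patterns were themselves noticed in the data. T cell receptor genes lay outside the planned comparisons. Trbv4 was the leading beta V segment in 66.2% (53.3 to 77.4) of 65 IL-27 CD8 T-like cells with such a UMI and in 20.3% (14.9 to 26.6) of 197 control cells. Trbv16 led in 43.7% and 6.15%, and Trbv19 in 29.4% and 4.62%. Eosinophil-like cells, another signal outside the planned classes of interest, made up 0.611% (0.466 to 0.785) of IL-27 cells and 0.0188% of control cells, a ratio of 32.4 (8.59 to 274).

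The smaller CD8 T-like share of the IL-27 matrix (ratio 0.412) was weighed first. With no doublets removed the ratio was 0.419 (0.322 to 0.542), which argues against uneven doublet removal as the cause. It does not bear on doublets left in the control matrix, where none had been called. With the 8% of cells with the highest doublet scores removed from each matrix, CD8 T-like cells numbered 152 and 68, or 1.56% and 0.740%. Without cells led by Trbv16, the leading segment of the control cells, it was 0.665 (0.492 to 0.894), which argues against a single expanded clone as the whole cause. Without the cells of the 3 segments that each led in over 20% of either matrix's cells (184 control and 50 IL-27 cells), 23 and 29 cells remained, 10 and 14 of them without a beta V UMI, and the ratio was 1.35 (0.752 to 2.44). The segments were picked for their frequency in these cells and few cells remained, so this value decides nothing. A few expanded clones and a smaller share across clones cannot be told apart here, a segment is not a clone, and an effect of IL-27 stays open.

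Interferon-stimulated genes were weighed next. The CD8 T-like class leaves out T/NK cluster 4, which scored highest for CD8 T cells and whose leading genes included Ifit1 and Ifit3. The median of the list medians over 7 classes was -0.41 (-0.48 to -0.30), with CD8 T-like cells apart from the other 6. With the length, GC and level trend removed it was -0.44 (-0.48 to -0.28), which argues against that trend as the whole cause. In cells without a UMI of 6 stress genes it was -0.28 (-0.52 to -0.26). The macrophage-like median was then -0.28 (-0.54 in all cells) and the dendritic-like median -0.21 (-0.33 in all cells). This argues only weakly against stress as the whole cause, because such cells may be low in UMIs and other stress genes were not used. Of the neutrophil-like cells, 1113 of 5058 in control and 1270 of 4082 in the IL-27 matrix had no such UMI. Subtracting free RNA estimated from neutrophil genes gave -0.37 (-0.47 to -0.27) over 6 classes, against -0.37 before. In NK-like cells the estimated share of free RNA was 0.170% in both matrices while the list median was -0.41. These values argue against free RNA as the whole cause. The profile of free RNA was taken from all cells, so its part in the macrophage-like, monocyte-like and dendritic-like medians stays open. With the length, GC and level trend removed, housekeeping genes had a median of -0.30 in Treg-like cells, beside -0.21 for interferon-stimulated genes. The 2 values were -0.29 and -0.44 in neutrophil-like, -0.21 and -0.35 in dendritic-like and 0.06 and -0.52 in macrophage-like cells. The Treg-like median is thus not set apart from a wider shift, to which part of the neutrophil-like and dendritic-like medians can also belong. A lower interferon tone in the tumours that received IL-27 is possible, but a difference between the 2 libraries or their mice may give the same values.

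The eosinophil-like cluster was weighed last. Its median of 570.5 UMIs in the IL-27 matrix lies near the filter. Counting barcodes with UMIs of at least 2 eosinophil markers, without clustering, gave 1 of 10784 control and 10 of 10183 IL-27 barcodes, a ratio of 10.6 (1.51 to 460). The interval is too wide to decide, so low-UMI droplets grouped by the clustering and a true difference in eosinophils cannot be told apart for this cluster. The cluster was absent under the stricter filter and without a mitochondrial limit.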

How the results depend on the processing

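Removal of the 8% of cells with the highest doublet scores, trend removal, the CD8 gate and the limit to Trbv4 cells were chosen after seeing the data, the rest before. No paired analysis was possible because each group is 1 matrix. The Treg-like share of T cells was higher in the IL-27 matrix under all 9 alternatives (ratios 1.33 to 1.53). All 9 count CD8 T-like cells among the T cells, so none separates this share from the smaller number of CD8 T-like cells. For class shares, 94 values stayed within the counting interval, 8 moved and 5 reversed. The stricter filter gave 0.793 for neutrophil-like, 1.39 for monocyte-like and 1.06 for tumour-like cells, monocyte-like cells had 1.37 with no mitochondrial limit and 1.39 with doublets kept, and removal of high doublet scores gave 1.03 for macrophage-like, 1.00 for tumour-like and 0.864 for endothelial-like cells. Endothelial-like cells had 0.882 with no mitochondrial limit and 0.841 at resolution 2.0, with no such class under the stricter filter, with doublets kept or at resolution 0.5. The CD8 gate gave 2.39% and 0.988%. Of values for the Treg genes, 95 stayed, 5 moved and none reversed: with the Foxp3 gate the log2 ratios were 0.13 for Foxp3, 0.56 for Il2ra, 0.70 for Ikzf2 and -0.48 for Ctla4, and trend removal gave 0.16 for Ikzf2. Of list medians, 525 stayed, 78 moved and 6 reversed. Treg identity was 0.035 with the trend removed. Interferon-stimulated genes in Treg-like cells had -0.55 both with no mitochondrial limit and with doublets kept, and in neutrophil-like cells -0.51 by mean CPM per cell. Removal of high doublet scores gave -0.10 for Th1 in Treg-like cells, and in CD8 T-like cells -0.36 for cytotoxic, -0.011 for Th1 and -0.16 for alternative macrophage genes, the last -0.45 with at least 100 UMIs. Trbv4 cells alone gave -0.32 for exhaustion and -0.092 for Th1. Proliferation in NK-like cells was -0.091 by mean CPM per cell and -0.14 without high doublet scores. Of named genes, 841 values stayed, 84 moved and 5 reversed: without high doublet scores Ccl4 had -1.35, Ccl3 -0.12 and Thbs1 -0.19 in CD8 T-like cells and Mt1 -0.61 in NK-like cells, Gzmf gave no value in NK-like cells, and Thbs1 had -1.32 in Trbv4 cells. Of list members named, 271 values stayed, 38 moved and 1 reversed, Gzmc in Treg-like cells with -0.67 without high doublet scores, where Ifng in CD8 T-like cells had 0.57 (main value 1.52). The cause of these differences was not tested. With naming minimums of 20 and 200 UMIs, 3 and 4 of 20 named Treg-like genes, 8 and 5 of 20 CD8 T-like genes and 20 and 20 of 20 neutrophil-like genes were named again. Of 10 genes per class, 3 and 2 were named again in NK-like and 10 and 4 in macrophage-like cells. In monocyte-like and dendritic-like cells 8 and 2 and 8 and 5 of 10 were. Depth limits Ifng in Treg-like cells to a bound and leaves the 79 CD8 T-like cells with wide intervals.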

Other observations

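The comparison of Trbv4 cells and the look at Treg-like segments were chosen after the results were seen. To ask whether the higher Ifng counts of CD8 T-like cells came from their mix of T cell receptors, cells led by Trbv4 were compared alone, 40 control cells with 481836 UMIs and 43 IL-27 cells with 524071 UMIs. In these cells Ifng stood at 45.7 and 210 CPM, a ratio of 4.60 (2.89 to 7.63), with 54.5% of the control and 74.5% of the IL-27 UMIs in 3 cells. Ccl4 had a ratio of 6.17 (4.76 to 8.12) and Xcl1, a chemokine gene that draws dendritic cells, had 1 and 87 UMIs, a ratio of 80.0 (13.98 to 3195), with 96.8% and 95.4% of their IL-27 UMIs in 3 cells. Gzmb was level (ratio 0.999, 0.914 to 1.09), while Gzmc (0.317), Tox (0.494) and, by under 1.5-fold, Prf1 (0.728) were lower. The myeloid gene Lyz2 was higher (8 and 42 UMIs, ratio 4.83, 2.24 to 11.9), so the subset also differs in transcripts of other cell types. Within this subset the exhaustion list had a median of -0.32. The mix of segments may thus not account for the lower Tox or the higher Ifng counts alone, although the Ifng counts rest on few cells and the cells of a segment can belong to different clones.

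Treg-like cells, unlike CD8 T-like cells, spread over many beta V segments, with Trbv13-2 the most frequent at 19.1% and 21.5%. The share of free RNA estimated from neutrophil genes was 0.133% and 0.445% in Treg-like cells, 0.165% and 1.36% in CD8 T-like cells, 0.170% in NK-like cells of both matrices, 6.45% and 4.26% in macrophage-like cells, 8.11% and 6.18% in monocyte-like cells and 3.22% and 3.01% in dendritic-like cells.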
